A study of Rattus norvegicus with 8 samples.

How the data were processed

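Liver RNA from female Wistar rats, an outbred laboratory strain, was measured on 8 Affymetrix Rat Gene 1.0 ST arrays, which read each transcript with many probes along its length. The labels name 4 groups with 2 arrays each. One group is the remaining liver 8 h after partial hepatectomy (PH), the surgical removal of about 2/3 of the liver. The other groups are livers of rats aged 2, 4 and 12 weeks. The age of the operated rats is not given in the sources used here, and no sham-operated group was analysed here. The 12-week livers therefore served as the comparison for the operated ones. Effects of surgery, age and time of day cannot be separated in that comparison. The titles call the arrays of a group biological replicates, while the design text speaks of duplicate processing. The p-values therefore measure the spread between these arrays, part of which may be technical.

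The deposited values are on a log2 scale and were made by the authors with robust multi-array averaging (RMA) in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, equalises the arrays and summarises the probes of a probe set. The versions and any filter are not given in the sources used here. Values ran from 1.32 to 14.23, and array medians lay between 5.98 and 6.17. No detection calls and no scan or batch information were used here. A signal near the bottom of the scale cannot be told from background by these values alone, and RMA compresses the change of such genes. The number of arrays limits the precision.

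The table held 29214 probe sets. The platform annotation listed 15633 of them with a gene, of which 15316 had 1 symbol and 317 several. The other 13581 were unnamed here. Symbols were updated through gene identifiers to the GRCr8 gene table, used for names only. Of the single symbols, 15291 matched a current gene and 2 were updated. Genes with several probe sets (528) were represented by 1 of them, which left 14511 genes. No genome build or coordinates came with the values. Members of gene families with near-identical sequences, such as Cyp2c, Cyp3a, Ces and Ugt genes, can share signal between probe sets and are uncertain.

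Each comparison was a contrast in 1 linear model of the 4 groups over the 8 arrays, fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes. The residual degrees of freedom were 4 and the prior added 4.27. A gene was called changed at a two-sided adjusted p (Benjamini-Hochberg over 14511 genes) under 0.05. Log2 differences are given with the moderated standard error (SE), and group values as mean ± SD with n = 2. Tested on simulated data for 8 h after PH against 12 weeks (10 simulations of 14511 genes, 200 of them changed), this model found 20% of the genes changed by 1 log2 unit, 94.8% of those changed by 2, 99.4% by 3 and 100% by 4. Of its calls, 6.3% were unchanged genes. The simulation gave a gene the same spread on all arrays. In the data the 12-week arrays varied more than the PH arrays (mean variance 0.233 against 0.0886). Lcn2, which differed by 4.79 in that comparison, was not called, so these shares do not tell how many large changes were missed.

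Before the data were examined, 29 gene lists were fixed, 20 of pathways and 9 of cell type markers, with 423 of 480 entries measured. The pathway lists were immediate-early, acute-phase, G1 regulators, DNA replication, mitosis, ribosome biogenesis, xenobiotic metabolism, bile acid synthesis and transport, cholesterol synthesis, lipogenesis, fatty acid oxidation and ketogenesis, gluconeogenesis, urea cycle and amino acid breakdown, fetal liver and imprinted growth, growth hormone and IGF axis, sex-dependent liver, circadian clock, heat shock and oxidative stress, respiratory chain, and hepatocyte transcription factors. The marker lists were erythroid, macrophage, neutrophil, lymphocyte, stellate and fibroblast, endothelial, cholangiocyte, pancreas and adipocyte markers. Some genes stand in 2 lists. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the 29 lists. With an estimated correlation camera called 0 lists in each of the 4 comparisons, and the lowest adjusted p was 0.1286 for PH, 0.131 for 2 against 12 weeks, 0.2105 for 4 against 12 weeks and 0.05904 for 2 against 4 weeks. The list calls therefore rest on the preset setting. The size of the correlation alone does not account for this. For bile acid synthesis and transport after PH the estimate was 0.0127, yet the camera adjusted p went from 7.4e-05 to 0.1851. fry, which asks whether the genes of a list move one way without comparing them with other genes, called 1, 9, 0 and 8 lists in the same order. Members were also counted with p adjusted over the list alone. The median, mean and test of a list differed in sign in 18 of the list results, 0 of them called. On simulated data for 8 h after PH against 12 weeks (14511 genes), camera called 0 of 290 unchanged lists. The simulated genes were drawn independently, so this cannot tell how often lists of correlated genes are called without a change. In the data the estimated correlation was 0.686 for cholesterol synthesis.

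The named genes follow a rule set before the data were examined. For each of the first 4 comparisons it takes the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between groups, skipping provisional LOC and RGD symbols and microRNA genes, and if fewer pass, those that pass. It adds up to 4 members of each list described with the smallest p, and Afp, Igf2, Ccnd1, Myc and Cyp7a1 in every comparison whatever their p.

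The alternatives were a filter at the median level, all probe sets, probe set means, quantile normalization, median centring, scaling to the 75th percentile, eBayes with trend and robust options, only the 4 arrays compared, a test without moderation, a 2-fold limit, an adjusted p under 0.01, the replicate number as a block, and leaving out each array. Array weights and the level of olfactory and related receptor genes as a covariate were added after seeing the data. The 2 comparisons against the same 12-week arrays share their chance values, and 100 draws of unchanged groups against shared controls gave the values expected with no effect, once with equal spread in all groups and, added after seeing the data, once with each group's own spread.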

Results

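The livers of rats at 2, 4 and 12 weeks of age and the remaining liver 8 h after partial hepatectomy (PH) were compared by their RNA levels. The study set regeneration after surgery beside stages of liver development. Each group had 2 arrays, and 14511 genes were tested. Values are RMA levels on the log2 scale. The arrays of a group correlated over genes with r = 0.980 for PH, 0.977 at 2 weeks, 0.975 at 4 weeks and 0.952 at 12 weeks. Genes are not independent replicates. The 12-week arrays stood furthest apart, with 1838 genes differing at least 2-fold between them against 432 for PH, 480 at 2 weeks and 621 at 4 weeks. The median of 1256 olfactory and related receptor genes, which liver is not known to use, was 4.74 and 3.91 on the 12-week arrays, 4.64 and 4.17 on the PH arrays, and between 4.01 and 4.06 on the other 4.

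The first comparison asked how the liver 8 h after PH differed from the 12-week liver. Without a sham-operated group, surgery, age and time of day cannot be separated in it. A2m, a protease inhibitor of the rat acute-phase response, was higher by 6.17 ± 0.31 (log2, SE; adjusted p = 4.2e-04), at 12.78 ± 0.29 (SD, n = 2) after PH against 6.62 ± 0.12 at 12 weeks. Tnfrsf21, a death receptor, rose by 2.58 ± 0.21 (adjusted p = 0.008275), and Gucy2c, a guanylate cyclase receptor, rose by 3.06 ± 0.34 (adjusted p = 0.0464). Arhgef19 fell by 2.46 ± 0.25 (adjusted p = 0.03931) and Cryl1 fell by 2.09 ± 0.23 (adjusted p = 0.0464). These 5 genes, 3 higher and 2 lower, were the calls in limma, and 872 genes had an unadjusted p under 0.05 where 725.6 are expected by chance.

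The acute-phase list was higher after PH (median 0.53, all 20 measured members above 0, camera adjusted p = 2.2e-14, adjusted p = 0.1286 with an estimated correlation). Of its members 1 rose, A2m, and 8 did so when adjusted over the list alone. Socs3, a feedback inhibitor of cytokine signalling, differed by 2.31 ± 0.28 (adjusted p = 0.05362), Lcn2, an iron-carrier binding protein, by 4.79 ± 0.62 (adjusted p = 0.0544) and Stat3 by 1.47 ± 0.23 (adjusted p = 0.1165). The ribosome biogenesis list was also higher (median 0.69, 19 of 20 members above 0, adjusted p = 1.7e-10, adjusted p = 0.3894 with an estimated correlation), with 0 members passing singly by limma or when adjusted over the list alone. Its members Ncl and Bop1 differed by 0.92 ± 0.22 and 1.18 ± 0.35 (Bop1 0.76 without the first 12-week array).

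Lipid and bile acid lists were lower after PH. Lipogenesis had a median of -0.87 with 15 of 16 members below 0 (camera adjusted p = 2.3e-09, adjusted p = 0.3672 with an estimated correlation). In it 0 members passed over all genes and 4 when adjusted over the list alone. Acacb, an acetyl-CoA carboxylase, differed by -2.09 ± 0.37, Pnpla3 by -1.84 ± 0.42 (-1.21 without the second 12-week array) and Gpam by -1.75 ± 0.27. Bile acid synthesis and transport had a median of -0.43 (adjusted p = 7.4e-05, adjusted p = 0.1851 with an estimated correlation), with 3 members lower when adjusted over the list alone. Nr0b2 differed by -1.68 ± 0.33, Slco1a4 by -1.17 ± 0.28 and Akr1d1 by -1.12 ± 0.32. Xenobiotic metabolism (median -0.38, adjusted p = 2.6e-04, adjusted p = 0.2242 with an estimated correlation, with Aldh1a1 -1.55 ± 0.36), cholesterol synthesis (median -0.43, adjusted p = 0.005811, adjusted p = 0.7497 with an estimated correlation, with Pmvk -1.40 ± 0.36, and -0.85 without the second 12-week array) and urea cycle and amino acid breakdown (median -0.18, adjusted p = 0.04992, adjusted p = 0.7497 with an estimated correlation) were lower too. In the last list Otc differed by -1.01 ± 0.29 and Agxt by 1.27 ± 0.28. Lymphocyte markers had all 12 members below 0 (median -0.64, adjusted p = 2.4e-06, adjusted p = 0.4146 with an estimated correlation), among them Cd3d at -1.15 ± 0.20.

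Cell cycle lists were not called at 8 h: G1 regulators (median 0.10, adjusted p = 0.6616), DNA replication (median 0.01, adjusted p = 0.6616) and mitosis (median -0.19, adjusted p = 0.07625). Ccnd1, the cyclin of the G1 phase, differed by -0.08 ± 0.28, and Myc by -0.08 ± 0.23. Afp (-0.54 ± 0.33), Igf2 (0.17 ± 0.39) and Cyp7a1 (0.17 ± 0.52) did not pass either. Without the first and the second 12-week array, Afp differed by -1.01 and -0.07, Ccnd1 by -0.48 and 0.32, Myc by -0.23 and 0.08 and Cyp7a1 by -0.33 and 0.66. The immediate-early list missed the threshold (median 0.17, adjusted p = 0.05931), and its member Junb differed by 1.91 ± 0.24 (adjusted p = 0.05362). Single members of further uncalled lists stood apart without passing over all genes: Nr1d1 (2.24 ± 0.35), Bmal1 (-2.30 ± 0.49) and Dbp (2.39 ± 0.73) of the circadian clock (for the last 2, -1.46 and 1.05 without the first 12-week array and -3.13 and 3.73 without the second), Hmox1 (1.95 ± 0.31) and Mt2A (2.40 ± 0.47) of the stress list, Cpt1a (1.88 ± 0.41) and Ehhadh (-1.42 ± 0.24) of fatty acid oxidation, and Hgf (1.11 ± 0.21). The adjusted p of the other lists lay between 0.07314, for the growth hormone and IGF axis, and 0.9468, for gluconeogenesis. The count of 5 became 2 without the first PH array, 1 without the second, 11 without the first 12-week array (4 higher, 7 lower) and 8 without the second (4 higher, 4 lower). Median centring left 2 calls, both higher, while scaling to the 75th percentile gave 11 (7 higher, 4 lower). The replicate number as a block gave 41 calls and the receptor-gene level as a covariate 50. A2m had an adjusted p under 0.05 in 17 of 18 alternatives, Tnfrsf21 in 14 of 18, Gucy2c and Arhgef19 in 9 of 17 each and Cryl1 in 8 of 18. These counts score the setting with the stricter limit at 0.05 as well. At an adjusted p under 0.01, 2 of the 5 calls were kept, A2m and Tnfrsf21. Of the 8 lists called, urea cycle was lost without the first PH or the first 12-week array and with the receptor-gene level as a covariate, and cholesterol synthesis without the second PH array. Without the second 12-week array both were lost with the bile acid and lymphocyte lists, and 5 lists were called.

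**Figure D1:**
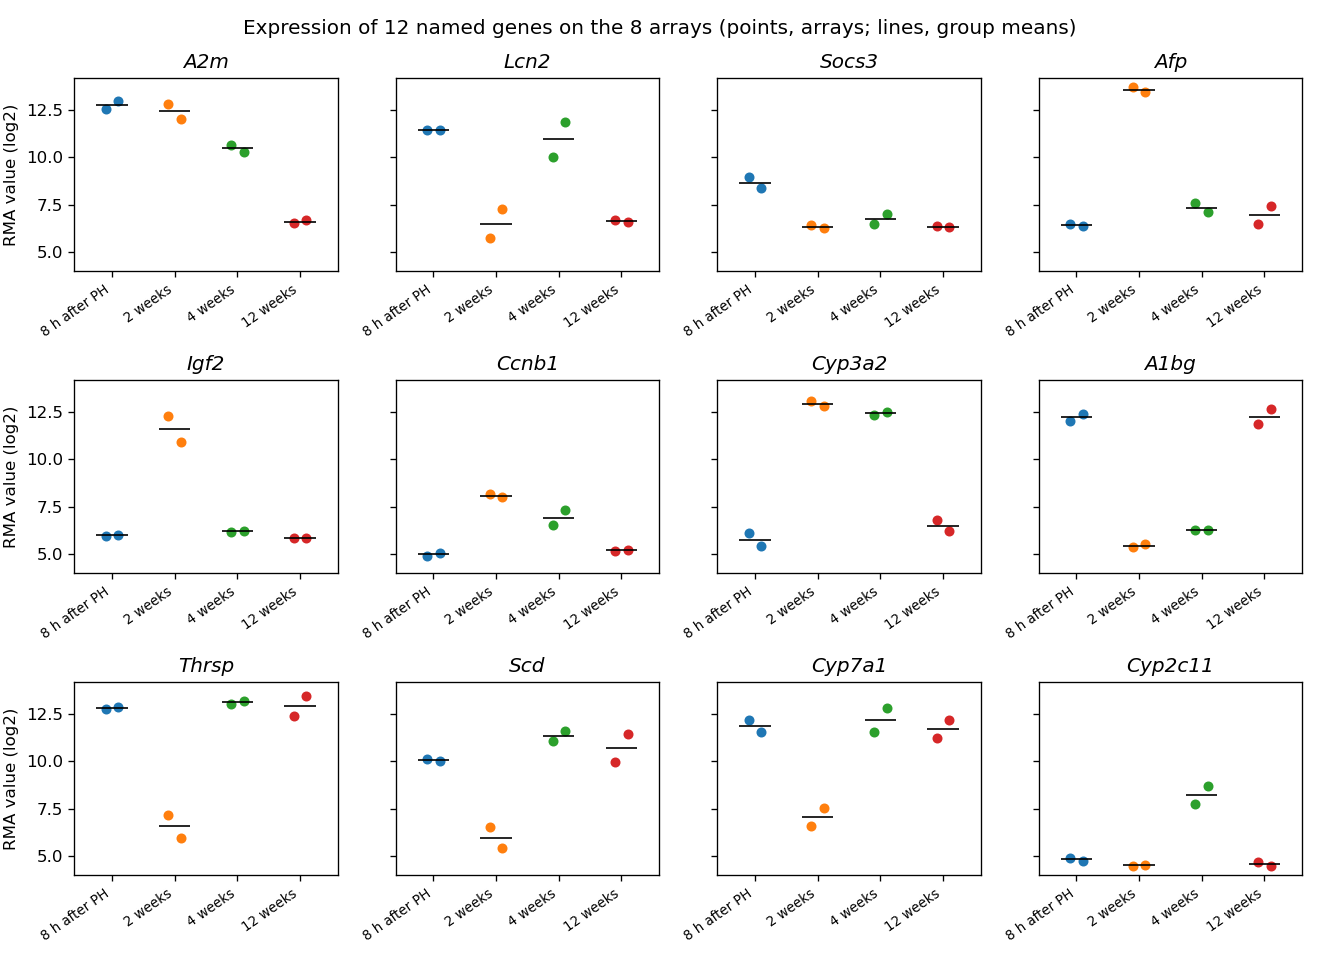
RMA values (log2, vertical axis) of 12 named genes on the 8 arrays, by group. Points are arrays and lines are means of n = 2. A2m averaged 12.78 after PH against 6.62 at 12 weeks, while Afp and Igf2 were high at 2 weeks only among the groups plotted.

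The comparison of 2 with 12 weeks set the youngest livers against the adult ones. Afp, the fetal serum protein, was higher by 6.58 ± 0.33 (adjusted p = 1.0e-04), at 13.57 ± 0.18 (SD, n = 2) at 2 weeks against 6.99 ± 0.66 at 12. The imprinted growth genes H19 and Igf2 rose by 6.30 ± 0.41 (adjusted p = 2.5e-04) and 5.75 ± 0.39 (adjusted p = 2.8e-04). Cyp3a2 rose by 6.41 ± 0.31, Alox15 by 5.82 ± 0.35, A2m by 5.80 ± 0.31, Lpl by 5.56 ± 0.31, Igfbp2 by 5.45 ± 0.39, Qpct by 5.09 ± 0.26 and Abcd2 by 5.02 ± 0.27. A1bg fell by 6.79 ± 0.30 (adjusted p = 1.0e-04). Further falls were Mettl7b (-6.60 ± 0.53), Rup2 (-6.37 ± 0.61), Thrsp (-6.35 ± 0.44), Ugt2a3 (-6.20 ± 0.34), Slc41a2 (-5.84 ± 0.35), Cyp3a9 (-5.67 ± 0.49), Hamp, the iron hormone hepcidin (-5.53 ± 0.62), Scd, a fatty acid desaturase (-4.69 ± 0.51), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-4.65 ± 0.52). In all, 323 genes were called, 187 higher and 136 lower at 2 weeks, and 1616 had an unadjusted p under 0.05 where 725.6 are expected by chance. The balance turned to 102 higher and 151 lower without the first 12-week array, to 46 and 55 without the first 2-week array, and to 113 and 118 among genes at or above the median level.

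Cell division genes were higher at 2 weeks. In the mitosis list 17 of 22 members rose (median 1.94, camera adjusted p = 3.1e-29, adjusted p = 0.131 with an estimated correlation), among them Ccnb1 (2.89 ± 0.28), Nusap1 (2.68 ± 0.30), Cdk1 (2.21 ± 0.24) and Cdc20 (2.13 ± 0.23). In DNA replication 3 of 21 rose, and 15 when adjusted over the list alone (median 1.01, adjusted p = 7.6e-13, adjusted p = 0.2148 with an estimated correlation): Rrm2 (2.89 ± 0.46), Mcm10 (2.22 ± 0.38) and Mcm6 (1.94 ± 0.40). In the G1 list 3 of 12 rose (median 0.93, adjusted p = 1.1e-06, adjusted p = 0.131 with an estimated correlation): Ccnd1 (2.19 ± 0.28), Ccne1 (1.92 ± 0.26) and Ccne2 (1.67 ± 0.34). Myc differed by 0.39 ± 0.23 (0.23 without the first 12-week array, 0.25 without the second 2-week array). The fetal liver and imprinted growth list had 7 of 13 members up (median 1.67, adjusted p = 1.9e-19, adjusted p = 0.131 with an estimated correlation), Meg3 among them (3.53 ± 0.40). Ribosome biogenesis was higher with 0 members passing singly by limma (median 0.43, adjusted p = 1.8e-04, adjusted p = 0.4502 with an estimated correlation).

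Lipogenesis was lower at 2 weeks, with 5 of 16 members down and 12 when adjusted over the list alone (median -1.82, adjusted p = 3.4e-15, adjusted p = 0.131 with an estimated correlation); besides Thrsp and Scd these included Acacb (-3.13 ± 0.37) and Me1, the malic enzyme (-2.35 ± 0.35). Cholesterol synthesis had all 15 members below 0 and 1 call, Dhcr7 (-2.85 ± 0.53; list median -1.30, adjusted p = 1.7e-07, adjusted p = 0.3041 with an estimated correlation). Fatty acid oxidation and ketogenesis was higher (median 0.63, adjusted p = 2.0e-06, adjusted p = 0.131 with an estimated correlation), with 0 members passing over all genes and 8 when adjusted over the list alone. Cpt1a differed by 1.76 ± 0.41 and Ppara by 1.55 ± 0.38. In bile acid synthesis and transport 3 of 17 fell (median -0.23, adjusted p = 5.0e-04, adjusted p = 0.131 with an estimated correlation): Cyp7a1, Slco1a4 (-3.08 ± 0.28) and Abcc2 (-2.34 ± 0.29). In xenobiotic metabolism 2 rose and 5 fell (median -0.33, adjusted p = 0.001003, adjusted p = 0.131 with an estimated correlation), with Cyp2c12 (-3.71 ± 0.23) and Cyp2j3 (-1.48 ± 0.22) among the falls. In the sex-dependent list 1 rose and 6 fell (median -1.52, adjusted p = 2.5e-06, adjusted p = 0.131 with an estimated correlation). As fixed, it shares Cyp2c7, Cyp2c11, Cyp2c12, Cyp3a2, Cyp3a9 and Cyp3a18 with xenobiotic metabolism, so the falls of both lists are not separate results. It mixes genes higher in males with genes higher in females, so its direction has no reading by sex.

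Markers of other cells also differed at 2 weeks. Erythroid markers were higher (3 of 12 rose, median 1.89, adjusted p = 3.5e-10, adjusted p = 0.131 with an estimated correlation), among them Ahsp (3.14 ± 0.56), Alas2 (2.74 ± 0.35) and Slc4a1 (2.01 ± 0.36), and stand beside the cell division lists as a measured shift. Stellate and fibroblast markers were higher (3 of 14 rose, median 1.26, adjusted p = 1.9e-08, adjusted p = 0.1695 with an estimated correlation): Reln (1.56 ± 0.30), Des (1.46 ± 0.29) and Hgf (1.30 ± 0.21). Neutrophil markers (median 0.89, adjusted p = 4.5e-05, adjusted p = 0.3041 with an estimated correlation, with Ngp 4.33 ± 1.18, at 11.28 on the first and 6.55 on the second 2-week array, so that it differed by 1.97 without the first and 6.70 without the second) and endothelial markers (median 0.35, adjusted p = 0.01175, adjusted p = 0.3102 with an estimated correlation) were higher and lymphocyte markers lower (median -0.77, adjusted p = 1.4e-05, adjusted p = 0.3041 with an estimated correlation, with Cd3d -0.96 ± 0.20), with 0 members passing singly by limma. In lists not called, Egr1 (1.56 ± 0.27), Sds (3.46 ± 0.63), Foxa3 (2.14 ± 0.29), Mt2A (2.33 ± 0.47) and Hmox1 (1.52 ± 0.31) rose, and Crp (-1.32 ± 0.23), Tdo2 (-2.74 ± 0.53) and Prlr (-2.30 ± 0.29) fell. Lbp differed by 1.39 ± 0.35 (0.92 without the second 12-week array). The adjusted p of the uncalled lists lay between 0.07997 and 0.8581. The count of 323 became 101 without the first 2-week array. Without the second 12-week array 13 lists were called, and bile acid, neutrophil, lymphocyte and endothelial lists were lost. Ribosome biogenesis was lost without the first 12-week array (15 lists) or the second 2-week array (16), and endothelial markers without the first 2-week array (16).

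The comparison of 4 with 12 weeks set the intermediate age against the adult livers. Cyp3a2 rose by 5.92 ± 0.31 (adjusted p = 2.5e-04), at 12.43 ± 0.11 (SD, n = 2) against 6.51 ± 0.42. Also higher were Alox15 (4.42 ± 0.35), H19 (3.91 ± 0.41), A2m (3.87 ± 0.31), Cyp2c11 (3.62 ± 0.32), Hao2 (3.60 ± 0.44), Slc22a8 (3.21 ± 0.33), Acsm3 (2.99 ± 0.33), the clock repressor Nr1d1 (2.94 ± 0.35), Pcolce (2.41 ± 0.25) and Egr1 (2.25 ± 0.27). A1bg fell by 5.98 ± 0.30, Rup2 by 5.80 ± 0.61, Cyp3a9 by 5.77 ± 0.49 and Lifr, a cytokine receptor, by 2.27 ± 0.23. In all 16 genes were called, 12 higher and 4 lower, while 649 had an unadjusted p under 0.05, fewer than the 725.6 expected by chance. Without the first 12-week array 9 were higher and 15 lower, and over all probe sets 8 and 8. Of the 16, 9 of the higher and 4 of the lower were also called in the same direction at 2 weeks. Independent lists would share 0.155 and 0.0375 genes, and part of the excess may come from the shared 12-week arrays. Afp (0.37 ± 0.33), Igf2 (0.36 ± 0.39), Ccnd1 (0.46 ± 0.28), Myc (0.89 ± 0.23) and Cyp7a1 (0.48 ± 0.52) did not pass. Without the first and the second 12-week array, Afp differed by -0.09 and 0.84 and Ccnd1 by 0.06 and 0.86, and without 1 array Cyp7a1 ran from -0.14 to 1.11.

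Mitosis genes were higher at 4 weeks as a list (all 22 above 0, median 0.97, adjusted p = 1.4e-24, adjusted p = 0.2105 with an estimated correlation), with 0 members passing over all genes by limma and 17 when adjusted over the list alone. Ccnb1 differed by 1.71 ± 0.28 and Nusap1 by 1.28 ± 0.30. DNA replication (median 0.23, adjusted p = 0.01095, adjusted p = 0.7085 with an estimated correlation) and G1 regulators (median 0.22, adjusted p = 0.03529, adjusted p = 0.4868 with an estimated correlation) were higher by less. Stellate and fibroblast markers (median 1.13, adjusted p = 9.2e-12, adjusted p = 0.2105 with an estimated correlation, with Lrat 1.22 ± 0.34, Des 1.06 ± 0.29, which was 0.66 without the first 4-week array, Hgf 0.92 ± 0.21), erythroid markers (median 0.89, adjusted p = 1.4e-06, adjusted p = 0.3088 with an estimated correlation, with Alas2 1.79 ± 0.35) and neutrophil markers (median 0.50, adjusted p = 0.01371, adjusted p = 0.5918 with an estimated correlation) were higher, and lymphocyte markers lower (median -0.55, adjusted p = 6.0e-04, adjusted p = 0.4868 with an estimated correlation, with Cd3d -0.71 ± 0.20). Acute-phase (median 0.26, adjusted p = 9.1e-05, adjusted p = 0.2105 with an estimated correlation, with Lcn2 4.27 ± 0.62), immediate-early (median 0.16, adjusted p = 0.002461, adjusted p = 0.2105 with an estimated correlation), xenobiotic metabolism (median 0.17, adjusted p = 6.0e-04, adjusted p = 0.2105 with an estimated correlation, with Cyp3a18 1.90 ± 0.40) and fetal liver and imprinted growth (median 0.37, adjusted p = 1.3e-05, adjusted p = 0.4584 with an estimated correlation, with Mest 1.74 ± 0.56) were higher. Urea cycle and amino acid breakdown was lower (median -0.12, adjusted p = 0.01095, adjusted p = 0.4868 with an estimated correlation, with Hal -2.01 ± 0.37). Over all genes 0 members passed in the DNA replication, G1, stellate and fibroblast, erythroid, neutrophil, lymphocyte and urea cycle lists. Lcn2, Cyp3a18 and Mest did not pass either. In xenobiotic metabolism 2 members rose, Cyp3a2 and Cyp2c11, and 1 fell, Cyp3a9. The uncalled lists had an adjusted p between 0.05972, for the sex-dependent list, and 0.9696. The count of 16 became 5 without the first 4-week array, where 10 lists were called and the immediate-early, G1 and lymphocyte lists were lost. The G1, DNA replication, urea cycle and neutrophil lists were lost without the second 4-week array (10 lists), and the first 3 of these without the first 12-week array (11). Without the second 12-week array 8 lists were called, and immediate-early, acute-phase, urea cycle, neutrophil and lymphocyte lists were lost. The G1 list was also lost among genes at or above the median level (adjusted p = 0.1163). Of the 12 called lists, 10 had enough members left there to be tested. With the receptor-gene level as a covariate the G1 (adjusted p = 0.2719) and DNA replication lists (adjusted p = 0.5464) were lost.

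The comparison of 2 with 4 weeks set the younger ages against each other. Afp was higher at 2 weeks by 6.21 ± 0.33 (adjusted p = 6.7e-04), Igf2 by 5.39 ± 0.39, Igfbp2 by 4.10 ± 0.39, Qpct by 4.06 ± 0.26, Lpl by 3.24 ± 0.31, Ldhb by 3.17 ± 0.46, Abcd2 by 3.06 ± 0.27, Meg3 by 3.02 ± 0.40, Vnn1 by 2.78 ± 0.41 and Grb10 by 2.76 ± 0.41. Thrsp was lower by 6.52 ± 0.44 in size (adjusted p = 0.001173). The other large falls were Scd (-5.36 ± 0.51), Cyp7a1 (-5.14 ± 0.52), Mettl7b (-4.65 ± 0.53), Slc41a2 (-4.49 ± 0.35), Lcn2 (-4.43 ± 0.62), Ugt2a3 (-4.15 ± 0.34), Glyat (-4.08 ± 0.33), Cyp2c12 (-3.74 ± 0.23) and Cyp2c11 (-3.70 ± 0.32). In all 66 genes were called, 22 higher and 44 lower at 2 weeks, and 1050 had an unadjusted p under 0.05.

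Lipogenesis was lower at 2 than at 4 weeks with 4 calls and 14 members lower when adjusted over the list alone (median -1.98, adjusted p = 9.4e-21, adjusted p = 0.1039 with an estimated correlation), including Me1 (-3.00 ± 0.35) and Acacb (-2.87 ± 0.37). Cholesterol synthesis (median -1.33, adjusted p = 2.3e-11, adjusted p = 0.249 with an estimated correlation, with Dhcr7 -2.82 ± 0.53, and -1.87 without the second 2-week array), bile acid synthesis and transport (median -0.21, adjusted p = 1.9e-07, adjusted p = 0.05904 with an estimated correlation, with Slco1a4 -3.09 ± 0.28), xenobiotic metabolism (median -0.59, adjusted p = 3.5e-09, adjusted p = 0.05904 with an estimated correlation, with Cyp2j3 -1.96 ± 0.22, Cyp3a18 -2.99 ± 0.40) and the sex-dependent list (median -1.66, adjusted p = 2.7e-15, adjusted p = 0.05904 with an estimated correlation, with Cyp2c13 -2.43 ± 0.28) were lower too. Mitosis (median 0.99, adjusted p = 1.6e-16, adjusted p = 0.1713 with an estimated correlation, with Cdc20 1.25 ± 0.23, Cdk1 1.20 ± 0.24), DNA replication (median 0.72, adjusted p = 2.3e-11, adjusted p = 0.256 with an estimated correlation, with Mcm10 1.75 ± 0.38), G1 regulators (median 0.69, adjusted p = 4.4e-05, adjusted p = 0.1713 with an estimated correlation, with Ccne1 1.69 ± 0.26, Ccnd1 1.73 ± 0.28) and fetal liver and imprinted growth (median 1.42, adjusted p = 1.5e-17, adjusted p = 0.1125 with an estimated correlation) were higher. Fatty acid oxidation and ketogenesis (median 0.61, adjusted p = 2.4e-08, adjusted p = 0.1237 with an estimated correlation, with Hadha 1.06 ± 0.24, Acaa2 1.20 ± 0.30), ribosome biogenesis (median 0.45, adjusted p = 3.3e-06, adjusted p = 0.3807 with an estimated correlation), erythroid markers (median 0.60, adjusted p = 4.7e-05, adjusted p = 0.2605 with an estimated correlation) and neutrophil markers (median 0.65, adjusted p = 0.009587, adjusted p = 0.5384 with an estimated correlation) were higher, and lymphocyte markers lower (median -0.31, adjusted p = 0.03261, adjusted p = 0.5971 with an estimated correlation). Over all genes 0 members passed in the cholesterol synthesis, mitosis, DNA replication, fatty acid oxidation, ribosome biogenesis, erythroid, neutrophil and lymphocyte lists. In the G1 list Ccne1 passed and Ccnd1 did not. Among genes at or above the median level the mitosis (adjusted p = 0.06377), G1 (adjusted p = 0.0612) and erythroid lists (adjusted p = 0.07624) were lost. Of the 14 called lists, 12 had enough members left there to be tested. In uncalled lists Foxa3 (2.23 ± 0.29) and A2m (1.93 ± 0.31) rose, Nr1d1 (-3.12 ± 0.35) and Crp (-1.53 ± 0.23) fell, and Myc differed by -0.51 ± 0.23. The adjusted p of the uncalled lists lay between 0.05646 and 0.9593. The count of 66 became 33 without the second 2-week array, 30 without the first 4-week array and 26 without the second. Neutrophil markers were lost without the first 2-week (17 lists) or first 4-week array (14), and lymphocyte markers without the first 2-week or the second 4-week array (18).

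**Figure D2:**
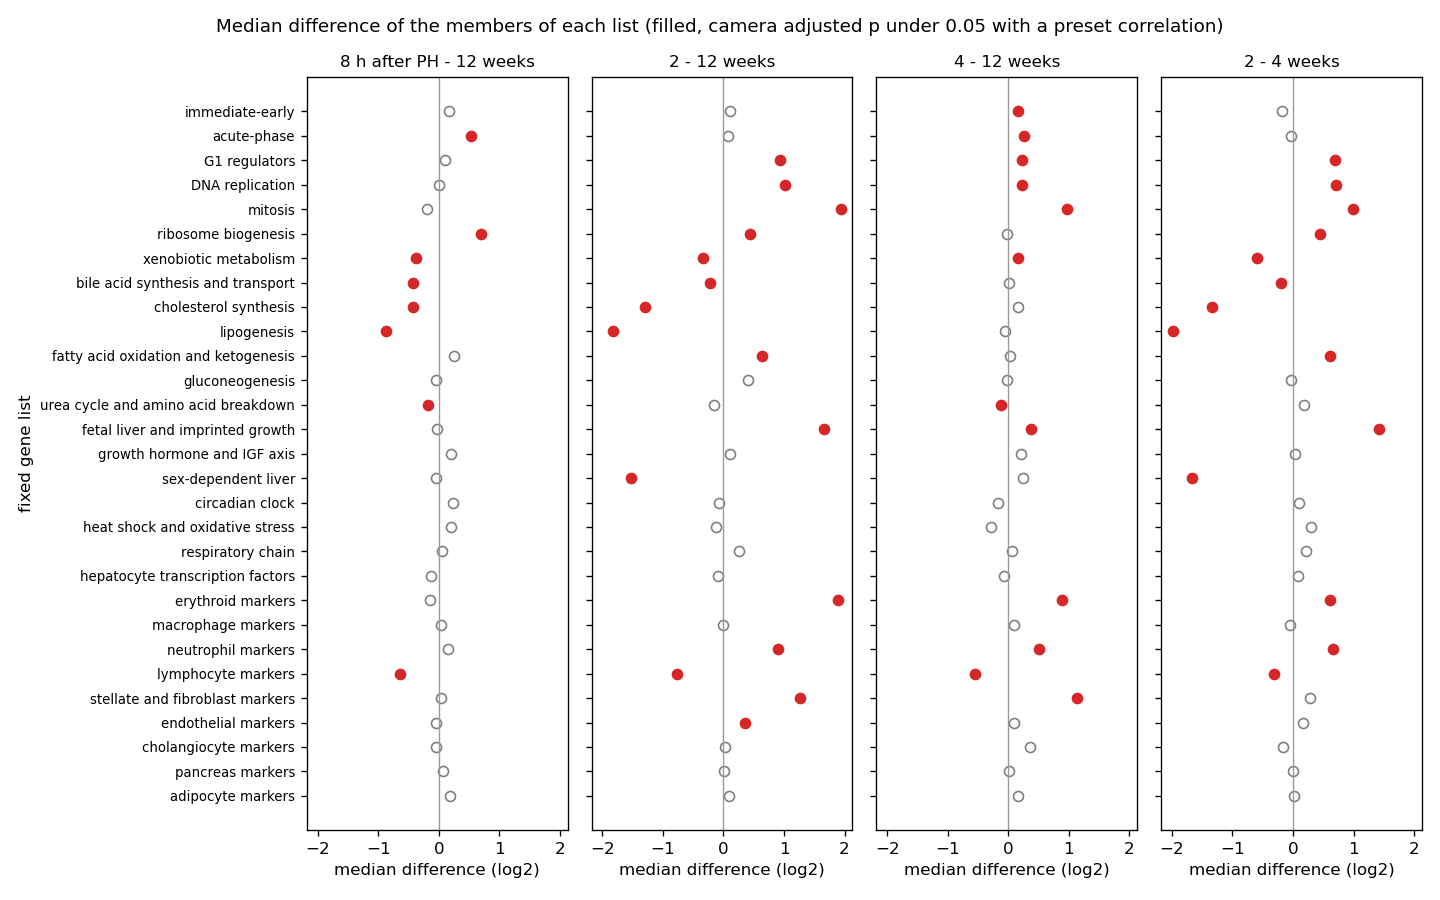
Median log2 difference (horizontal axis) of the measured members of each of the 29 fixed lists in 4 comparisons. Filled points passed camera with a preset correlation. With an estimated correlation 0 lists passed in each comparison. Mitosis had a median of 1.94 at 2 against 12 weeks and -0.19 at 8 h after PH, and lipogenesis -1.82 and -0.87.

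The operated livers were also set against the young ones. Against 2 weeks, 313 genes were called, 115 higher and 198 lower after PH. At an unadjusted p under 0.05 there were 1685 against 2 weeks and 1473 against 4 weeks. Afp (-7.12 ± 0.33, adjusted p = 7.3e-05), Igf2 (-5.59 ± 0.39, adjusted p = 3.9e-04) and Ccnd1 (-2.27 ± 0.28, adjusted p = 0.007105) were lower after PH and Cyp7a1 was higher (4.82 ± 0.52, adjusted p = 0.003361), while Myc differed by -0.46 ± 0.23. Against 4 weeks, 45 genes were called, 17 higher and 28 lower. The balance turned to 159 higher and 91 lower with the receptor-gene level as a covariate, to 12 and 10 over all probe sets and to 4 and 2 without the first PH array. Afp (-0.91 ± 0.33), Igf2 (-0.20 ± 0.39), Ccnd1 (-0.54 ± 0.28), Myc (-0.97 ± 0.23) and Cyp7a1 (-0.32 ± 0.52) did not pass. Ccnd1 differed by -0.23 with the receptor-gene level as a covariate and Igf2 by -0.08 with quantile normalization, and without 1 array Cyp7a1 ran from -0.94 to 0.31. The count of 313 became 72 and 94 without the first and second PH array and 88 without the first 2-week array. The count of 45 became 6 and 7 without the first and second PH array and 6 and 10 without the first and second 4-week array. Median centring gave 14 higher and 15 lower.

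The last comparison asked how far the differences after PH overlapped with those of the young livers. Of the 5 genes called after PH, A2m was also higher at 2 and at 4 weeks, and Arhgef19 and Cryl1 were also lower at 2 weeks, all against the same 12-week arrays. Independent lists would share 0.0387 higher and 0.0187 lower genes with 2 weeks, and 0.00248 higher genes with 4 weeks. Of the 8 lists called after PH, 6 were called in the same direction at 2 weeks (ribosome biogenesis higher, and xenobiotic metabolism, bile acid, cholesterol synthesis, lipogenesis and lymphocyte lists lower), where independent calls among the 29 lists would share 0.69 higher and 1.24 lower. At 4 weeks 3 were (acute-phase higher, urea cycle and lymphocyte lists lower, against 0.69 and 0.414), and xenobiotic metabolism was called the other way. All of these list calls were lost with an estimated correlation (adjusted p of at least 0.1286 after PH, 0.131 at 2 weeks and 0.2105 at 4 weeks), and part of the excess may come from the shared 12-week arrays. Across genes, the differences after PH correlated with those at 2 weeks at r = 0.339 (covariance 0.0791, the same sign in 64.3% of genes) and with those at 4 weeks at r = 0.213 (covariance 0.0333, 59.2%). Without the first and the second 12-week array r was 0.461 and 0.617 for 2 weeks and 0.482 and 0.599 for 4 weeks, and without the second PH array 0.216 and 0.108. Without the second 4-week array it was 0.111. Unchanged groups against the 2 shared controls gave r = 0.502, covariance 0.052 and 66.7% when all groups varied equally. The 12-week arrays varied more than the others (mean variance 0.233 against 0.0886 after PH, 0.101 at 2 and 0.110 at 4 weeks). With each group given its own variance, unchanged groups gave r = 0.711, covariance 0.117 and 75.1% for 2 weeks and r = 0.702, covariance 0.117 and 74.7% for 4 weeks, above the observed values. With a separate 12-week array for each comparison, r was -0.0292 and -0.176 for 2 weeks and -0.285 and -0.326 for 4 weeks, so the positive sign was not kept. This rests on the same spread between the 12-week arrays as the simulation with each group's own variance, so it is not a separate check. Changes of a group's own can lower r, and the simulated groups held none.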

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

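All tests of explanations in this part were chosen after the values they bear on had been seen. The following genes differed between 2 and 4 weeks in limma, with mean differences from 12 weeks of opposite sign at the 2 ages: Cyp2c11 (2 minus 4 weeks -3.70, adjusted p = 0.003219), Cyp3a18 (-2.99, adjusted p = 0.02008), Lcn2 (-4.43, adjusted p = 0.02398), Nr1d1 (-3.12, adjusted p = 0.009586), Sult1e1 (-1.69, adjusted p = 0.04139), Tsx (-3.27, adjusted p = 0.01979) and Wfdc21 (-3.42, adjusted p = 0.004063). Only genes that also differed at least 2-fold in the mean between 4 and 12 weeks were listed. Opposite movement from the 12-week level is not shown for any of the genes listed. At 2 weeks the differences of Cyp2c11 (-0.08), Sult1e1 (-0.09), Lcn2 (-0.15) and Nr1d1 (-0.18) were smaller than their SE, and only Wfdc21 passed (-2.15, adjusted p = 0.01374). At 4 weeks Cyp2c11 (adjusted p = 0.005702) and Nr1d1 (adjusted p = 0.02579) passed, and the others did not (adjusted p between 0.07081 for Lcn2 and 0.4987 for Wfdc21). Sult1e1, Tsx and Wfdc21 lie outside the rule for named genes and were chosen after their values were seen.

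Probe sets without a single gene name here, 13898 in number, were left out of the comparisons. Tested with all others in limma, 0 of them were called at 8 h after PH against 12 weeks, 84 at 2 against 12 weeks (39 higher, 45 lower), 4 at 4 against 12 weeks (0 higher, 4 lower) and 17 at 2 against 4 weeks (3 higher, 14 lower).

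Cyp2c11, in adult rats a male-specific cytochrome, read 7.76 and 8.71 on the 4-week arrays and between 4.49 and 4.93 on the other 6. Signal from its abundant relative Cyp2c12 is argued against: on 4 arrays of other groups with Cyp2c12 within 0.5 of its 4-week mean, the highest Cyp2c11 value still lay at -3.30 from the 4-week mean. A property of the 4-week liver itself was not tested. On the liver genes examined here, male animals in the 4-week group, against their labels, stay possible. Cyp2c12, which adult males lack, differed by 0.0274 between 4 and 12 weeks but may not yet differ between the sexes at that age. Genes of the sex chromosomes were not examined for this question. Cyp2c13 (5.75 and 6.10 at 4 weeks against 5.22 and 5.69 at 12) and Cyp2a2 (5.60 and 5.51 against 5.75 and 5.43), both also higher in males, did not settle it, since levels at or below the 12-week mean on both 4-week arrays, which would have argued against males, were found in neither gene. Of the 12 measured genes of the sex-dependent list (adjusted p = 0.05972), Cyp3a2, Cyp2c11 and Hao2 rose and A1bg and Cyp3a9 fell at 4 weeks, of which Cyp3a2, A1bg and Cyp3a9 did the same at 2 weeks, and Sult1e1 (5.15 and 5.78) and Cyp3a18 (11.42 and 11.51) read higher on the 4-week arrays than on any other without passing against 12 weeks.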

How the results depend on the processing

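The array weights, the receptor-gene covariate, leaving arrays out of the overlap and simulated groups with their own spread were chosen after seeing the data. Calls for PH against 12 weeks (5), 2 against 12 (323), 4 against 12 (16), 2 against 4 (66), PH against 2 (313) and PH against 4 weeks (45) became 0 in each without moderation (limma's fit with plain residual variance), where 778, 1402, 617, 998, 1459 and 1211 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.05515. They became 2, 109, 6, 31, 104 and 8 at an adjusted p under 0.01. With only the 4 arrays compared they moved to 2 for PH against 12, 140 for 2 against 12, 7 for 4 against 12 and 109 for PH against 4 weeks. All probe sets gave 3 for PH against 12 and 22 for PH against 4 weeks. Median centring gave 2 and 29 for these, and the 75th percentile 11 and 75. Array weights gave 2, 181, 10, 116, 587 and 159. The receptor-gene covariate gave 50 for PH against 12, 140 for 2 against 4 and 250 for PH against 4 weeks. The stricter limit calls fewer genes by construction. For the other settings the cause was not tested. Leaving out 1 array, with a lone array assumed to vary like the other groups, gave 1 to 11, 101 to 382, 5 to 24, 26 to 46, 72 to 242 and 6 to 10 calls. Centring and the 75th percentile shifted a comparison by between -0.0868 and 0.068.

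Whether the replicate numbers pair the samples stays open, and the main model holds no block for them. The deviations of arrays with the same number correlated between 0.0229 (2 with 12 weeks) and 0.568 (PH with 12 weeks). Every pair of groups lay above 0, but not every pair above 0.1. Of 24 pairings of an array with another group, 19 were closer to its own number, a hint from the data only. With the replicate number as a block the calls were 41, 515, 30, 129, 498 and 143, and calls shared with PH rose from 3 to 13 for 2 weeks and from 1 to 4 for 4 weeks.

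Lists called by camera (8, 16, 12 and 14) became 0 in all 4 comparisons with an estimated correlation, and 1, 9, 0 and 8 with fry. The filter at the median level lost the G1, mitosis and erythroid lists at 2 against 4 weeks and the G1 list at 4 against 12 weeks. Only 7, 14, 10 and 12 of the called lists had enough members left after this filter to be tested. The other called lists were neither kept nor lost by it. The receptor-gene covariate lost the G1 and DNA replication lists at 4 against 12 weeks and the urea cycle list at PH against 12 weeks. Leaving out 1 array gave 5 to 12, 13 to 16, 8 to 12 and 14 to 18 lists. The correlation of PH with 2 weeks turned from 0.339 to -0.0292 and -0.176 with unshared 12-week arrays, and with 4 weeks from 0.213 to -0.285 and -0.326, where the shared control is removed by construction. Leaving out 1 array gave 0.216 to 0.617 and 0.108 to 0.599. With each group given its own spread, the simulated values for unchanged groups moved from r = 0.502 to 0.711 (2 weeks) and 0.702 (4 weeks), from a covariance of 0.052 to 0.117 in both, and from 66.7% of genes with the same sign to 75.1% and 74.7%, because the shared 12-week arrays varied more.

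Of 3088 values of named genes under the alternatives, 2615 kept direction and side of the threshold, 415 lost the call, 49 gained it and 9 changed sign (all uncalled, without 1 array). Without 1 array, the values for PH against 12 weeks ran from -0.478 to 0.320 for Ccnd1, from -0.326 to 0.659 for Cyp7a1 and from -0.231 to 0.0801 for Myc. For 4 against 12 weeks they ran from -0.143 to 1.11 for Cyp7a1 and from -0.0944 to 0.843 for Afp, and for PH against 4 weeks from -0.943 to 0.310 for Cyp7a1. In all, 154 of the lost calls came from leaving out 1 array. The cause was not tested. Signal over background is not known without detection calls, which limits the genes near the bottom of the scale.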

Other observations

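All tests in this part were chosen after the values they bear on had been seen. Some genes read far higher on part of the arrays than on the others. RT1-N2, a class I histocompatibility gene, read 11.59 on the first and 6.02 on the second 12-week array, 10.50 and 10.02 after PH, and between 5.90 and 6.35 at 2 and 4 weeks. Ugt2b read 11.65 on the second 12-week array and between 3.87 and 5.44 on the other 7. Spp1, a cholangiocyte marker, read 11.77 on the first 4-week array and 5.83 on the second. These genes were chosen after their values were seen.

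The 12-week arrays differed more than those of any other group. Among 7254 genes at or above the median level, receptor genes left out, 1070 differed at least 2-fold between them against at most 501 in another group. This count cannot tell whether non-specific signal alone was at work. On the first 12-week array the 95th percentile of receptor genes was 6.37, above the median of all its probe sets (6.15). Its quartiles also lay closer together (5.08 and 7.63 against 4.70 and 7.85 on the second). Non-specific signal therefore stays open for these genes. For genes not expected in liver it stays open: the 9 pancreas markers had a median difference of 0.37 (array 1 minus 2) against 0.34 in size in the widest other group, a margin smaller than the one demanded, which was set after this value was seen, although the receptor-gene median differed by 0.83. Loss of short transcripts is consistent with the lower ribosomal protein genes (67 genes, median -0.55, below all of the matched random lists, whose median was -0.25). Livers taken at different times of day would go with the clock list. Its median absolute difference was 1.52 over 15 genes, above all of the matched random lists, whose median was 0.44. The random lists were matched on mean level only, and transcript length was not used. Genes that vary together can fall outside such lists, so both explanations stay open and may act together.

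The clock list was called by camera in none of the 4 comparisons tested (adjusted p between 0.2561 and 0.9593). It joins genes of opposite phase, whose changes can cancel in a directional test. The mixed form of fry, which ignores direction, gave an adjusted p of 0.1305 for PH against 12 weeks and 0.595 for 2 against 12. It gave 0.001594 for 4 against 12 and 0.04055 for 2 against 4 weeks. A candidate explanation for the values of its members is that the livers were collected in different clock phases. The mean of Bmal1, Npas2 and Clock and the mean of 7 genes of the opposite phase correlated at r = -0.856 over the 8 arrays (exact permutation p = 0.009177, adjusted p = 0.03671 over the 4 forms computed), but Spearman's rho was -0.595 (exact permutation p = 0.1323, adjusted p = 0.1764). Without the first 12-week array r was -0.652 (exact permutation p = 0.1109, adjusted p = 0.1764), and without the 2 arrays farthest from the median, that one and the first PH array, it was -0.410 (exact permutation p = 0.4444, also after adjustment). Leaving out the extremes narrows the range and leaves few arrays, so these values exclude nothing, while the permutations treat the 8 arrays as exchangeable although they form 4 groups, so differences between groups alone can give a low p. The low p rests on those arrays and a difference in phase stays open, where the demand that the relation hold in all of these forms was set after the first value was seen.

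A further hypothesis is that the operated rats were nearer to 12 than to 4 weeks of age. Over the 15 genes called between 4 and 12 weeks other than A2m, the operated arrays lay at a median position of 0.0359 on the way from the 12-week (0) to the 4-week (1) mean, with 14 of 15 below the midpoint and Nr1d1 at 0.76. The position of the 322 genes called between 2 and 12 weeks other than A2m had a median of 0.10. This is consistent with adult animals, but a response to surgery that moves these genes was not tested. A2m, at 12.57 and 12.99 after PH, was set aside because it was already seen to be high.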
